A study of Rattus norvegicus with 9 samples.

How the data were processed

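RNA from the left ventricle of Sprague-Dawley rats was sequenced after 28 days of saline, of angiotensin II (Ang II), or of Ang II with sodium butyrate (NaBu), with 3 libraries in each of the 3 groups. Ang II is a peptide hormone that raises blood pressure and is infused in rodents to produce cardiac fibrosis. NaBu is the sodium salt of a short-chain fatty acid that inhibits histone deacetylases. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase I and made into libraries with a TruSeq RNA kit for Illumina sequencing. The labels give an age of 8 weeks plus the 28 days, and no dose. They do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which can be technical in part.

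The authors deposited 1 table of estimated counts per group, with 1 line per transcript, and per the file headers each table gives a transcript ID, a gene name and 1 column per library. The saline table holds the same kind of deposited estimated counts, with a stray line-end character inside its last column that was stripped on reading. All 9 columns held 55767 whole numbers of at least 0 with unequal totals, so rounding to whole numbers changed nothing. Low values piled up near multiples of 4, so 1 sequenced fragment was worth about 4 estimated counts. The values were used as deposited, and dividing them by 4 was an alternative. Per the submitters' processing notes the reads were handled with Bowtie 0.12.2 and the build mm8, which is a mouse build, while the transcript IDs are rat RefSeq IDs. The counting tool, the annotation version and any use of strand are not given in the sources used here, so reads shared between paralogs or overlapping genes cannot be assigned with certainty. Each table holds a single group, so a difference in processing between tables and a difference between groups are confounded. The NaBu columns carry the numbers 2, 4 and 6, which match no number of the other groups, and are named by those numbers. All per-library columns were used.

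The values of the transcripts of each gene name were summed, which gave 22608 genes from 55767 transcripts. Total estimated counts were 34022912, 32999828 and 29284780 in saline replicates 1, 2 and 3, 31367765, 32858797 and 42742628 in Ang II replicates 1, 2 and 3, and 38567961, 38865038 and 49865446 in NaBu replicates 2, 4 and 6. The common biological coefficient of variation was 0.256. Levels are in CPM, relative to the library total scaled by TMM, as mean ± SD.

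Groups were compared with edgeR 4.0.16 (quasi-likelihood test, TMM scaling with factors from 0.887 to 1.14, filterByExpr) in R 4.3.3, with all 3 groups in the fit so that they share 1 estimate of the spread. This left 15467 genes. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05, and adjusted p-values of single genes are from this test unless another tool is named. Log2 fold changes used a prior count of 0.125 and are given with their standard error (SE). Gene lists, 36 in number, were tested over members with a mean of at least 1 CPM with camera (preset and estimated correlation) and fry from limma 3.58.1, adjusted over the lists. Camera asks whether a list is shifted relative to the other genes. A call lost with the estimated correlation does not by itself show a high correlation between members. That correlation was 0.019 for endoplasmic reticulum stress genes (NaBu against Ang II), where the camera adjusted p went from 0.0198 to 0.61. The named genes of each comparison are the 10 largest changes in each direction among called genes with no overlap between the groups, a mean of at least 5 CPM and a gene symbol that is not an unnamed locus; 13 genes tied to fibrosis, hypertrophy and histone deacetylation; and up to 2 members at each end of a list. Comparisons, tests, gene lists and the naming rule were fixed before the data were examined. Genes named outside the rule are called list members and genes named for a pattern, chosen after their values were seen. Some genes that the rule names are not reported here.

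The scripts were tested on simulated counts for 15467 genes with the means and library sizes of these samples. edgeR recovered 22.4% of 67 genes changed 1.5-fold, 67.2% of 67 changed 2-fold and 93.9% of 66 changed 4-fold for Ang II against saline, with 4 false calls. The shares were 17.9%, 62.7% and 93.9% with 8 false calls for NaBu against Ang II, and 16.4%, 64.2% and 97% with 12 false calls for NaBu against saline. DESeq2 made 36, 47 and 51 false calls in the 3 comparisons. Each simulated gene had the same spread in all groups, while the real saline libraries were less alike than the others. Simulated counts also moved in steps of 1, while 1 real fragment was worth about 4 counts. The gene rates therefore do not give the rate of false calls in the real data. A shift of 1.5-fold planted in 1 list of 40 genes was found in each comparison by camera with its preset correlation. Camera also called 1 of the 35 unplanted lists for NaBu against Ang II and 0 for the others. The simulated genes were drawn independently, while the estimated correlation within the real lists reached 0.844 (sarcomere, Ang II against saline). These list rates therefore do not give the rate of false list calls in the real data.

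Alternatives fixed before the data were examined were other prior counts, other filters on low counts, other scalings, the highest transcript of each gene, leaving out each library, a replicate block, DESeq2 1.42.0 and fits of only the 2 groups compared. Further alternatives were added after the data had been seen: leaving out ribosomal RNA genes, dividing counts by 4, leaving out genes listed at 0 in any library, thinning to the smallest library, removing a trend with genomic span, and leaving out saline replicates 2 and 3. Gene span and current symbols came from a RefSeq table of another rat assembly (GRCr8), which gave a span for 91.2% of the tested genes. No coordinates were used. GC content was not analysed here because no genome sequence was given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.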

Results

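RNA-seq of the left ventricle was compared between rats given saline, Ang II, or Ang II with NaBu for 28 days, with 3 libraries per group. Total estimated counts ranged from 29284780 in saline replicate 3 to 49865446 in NaBu replicate 6, and 15467 genes were tested. Within groups, log-scaled expression correlated across genes with r from 0.936 to 0.968, and the 3 saline libraries were less alike (0.936 to 0.946) than the 3 NaBu libraries (0.963 to 0.968). Ribosomal RNA took between 7.99% and 18.81% of the counts, with the highest share in saline replicate 3. The mitochondrial ribosomal RNA mt-Rnr2 took 6.46% to 7.56% of the counts in the NaBu libraries, less than in each Ang II library (8.07% to 11.84%) and each saline library (9.72% to 15.67%). The cause was not tested.

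Saline replicate 2 stood apart through atrial transcripts. Nppa (atrial natriuretic peptide) was at 3460 CPM in it and between 22.9 and 186 CPM in the other 8 libraries. Myl7, the atrial myosin regulatory light chain, was at 789 CPM against at most 27.2, Myl4 at 561 against at most 17.3, Sln (sarcolipin, a regulator of the calcium pump) at 173 against at most 4.01 and Bmp10 at 646 against at most 22.2. All 9 measured members of the atrial list were highest in this library, with a median log2 ratio of 2.94 to the other libraries. The ventricular transcripts Myh7 (5010 CPM against 12500 to 16000), Myl2 (240 against 465 to 940) and Myl3 (997 against 1960 to 3820) were lower in it than in each other library. In the same library the median log2 ratios were -0.70 for oxidative phosphorylation, -0.70 for fatty acid oxidation, 0.48 for fibroblast markers and 0.38 for collagen matrix genes. Saline replicate 3 had the highest collagen matrix values, with a median log2 ratio of 0.62 and 18 of 30 members highest there. It also had a median log2 ratio of 0.64 for the atrial list. Outside saline replicate 2, Nppa (186 CPM), Myl7 (27.2), Myl4 (17.3), Sln (4.01), Bmp10 (22.2) and Stard10 (12.5) were highest there. Dkk3, Tbx5, Nr2f1 and Nr2f2 were higher in at least 1 other library, such as Dkk3 at 102 CPM in NaBu replicate 2 against 33.8. Ang II replicate 1 stood apart from Ang II replicates 2 and 3. Its median log2 ratios were -0.38 for oxidative phosphorylation (-0.07 and -0.03 in the other two), -0.45 for fatty acid oxidation (0.04 and 0.00) and -0.32 for glycolysis (-0.05 and -0.07). Endothelial markers (0.30, 8 of 15 highest there) and interferon response genes (0.33, 12 of 22 highest there) were high in it.

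**Figure D1:**
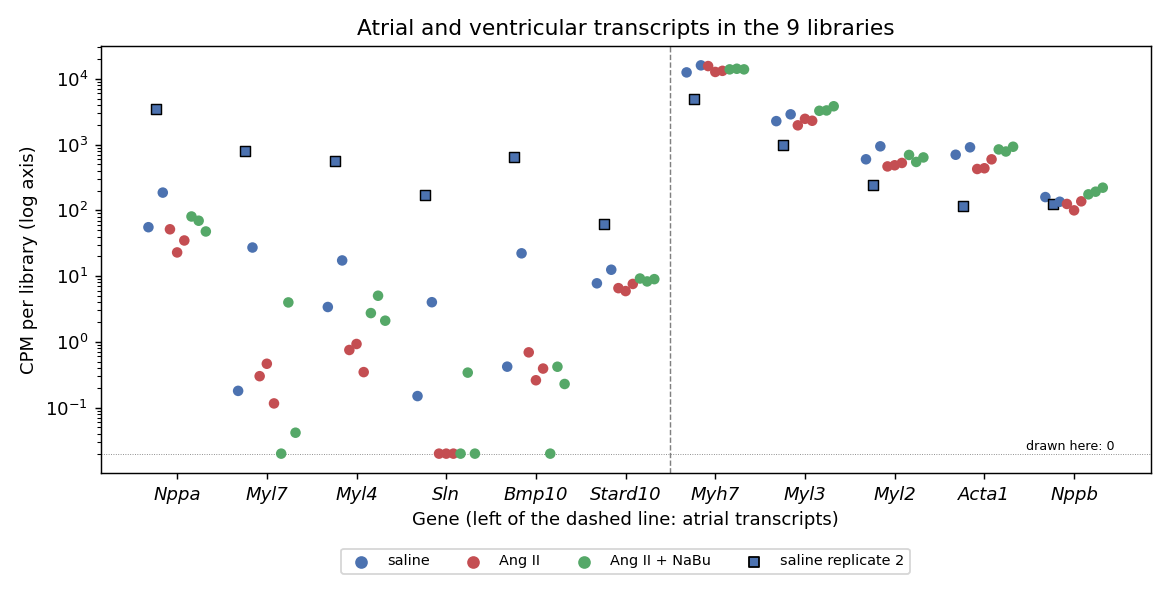
CPM of each of the 9 libraries on a log axis for atrial transcripts (left of the dashed line) and ventricular transcripts (right); each point is 1 library, squares mark saline replicate 2, and values of 0 are drawn on the dotted line. Saline replicate 2 has the highest value of each atrial transcript drawn, such as 3460 CPM of Nppa, and the lowest of Myh7, at 5010 CPM.

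The comparison of Ang II with saline asks which ventricular genes differ after 28 days of the hormone. No collagen gene was called as higher with Ang II in edgeR, and Col1a1 and Col3a1 averaged lower. Col1a1, a chain of the main fibrillar collagen, averaged 307 ± 24.4 CPM with Ang II and 504 ± 164 CPM with saline (SD, n = 3), a log2 difference of -0.71 (SE 0.218, edgeR adjusted p = 0.74), and Col3a1 averaged 1119 ± 37.9 against 1525 ± 439 CPM. Ctgf, a matricellular growth factor induced by TGF-beta, was lower in each Ang II library than in each saline library, at 45.8 ± 1.82 against 75.8 ± 12 CPM (log2 -0.73, SE 0.149), with an adjusted p of 0.443 in edgeR and 0.00521 in DESeq2 (0.00521 to 1 over the alternatives). Postn (periostin, a matrix protein of activated fibroblasts) averaged 9.34 ± 0.633 against 39.9 ± 44.9 CPM, where saline replicate 3 alone was at 91.7 CPM. The hypertrophy markers Nppb (120.7 ± 19 against 139.8 ± 17.3 CPM), Myh7 (log2 0.31, SE 0.319) and Myh6 (log2 -0.14, SE 0.116) did not pass the test. Neither did Acta2 (log2 -0.53, SE 0.353), Tgfb1 (0.05, SE 0.148) or Hdac5 (0.05, SE 0.089). Nppa averaged 36.4 ± 14.4 against 1235 ± 1932 CPM, with no overlap between the groups (edgeR adjusted p = 0.703; DESeq2 adjusted p = 0.018, and 0.018 to 1 over the alternatives). Its log2 difference was -5.09 (SE 1.28) with all libraries and -1.73 (SE 0.448, adjusted p = 0.36) without saline replicate 2. Saline replicate 3, with Nppa at 186 CPM, stayed in that fit. Ptgs2 (cyclooxygenase-2) was at 0.581 ± 0.143 against 2.64 ± 1.89 CPM, and Hdac6 was listed at 0 in 5 of the 9 libraries, so no level is given for it.

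No gene was called between Ang II and saline with edgeR (0 rose and 0 fell of 15467). At an unadjusted p under 0.05 there were 918 genes where chance gives 773, the smallest adjusted p was 0.252, and the groups did not overlap in 9.9% of genes where chance gives 10%. DESeq2 called 57 genes, of which 23 rose and 34 fell. Leaving out single libraries gave few calls: 4 rose and 3 fell without saline replicate 1, 1 rose without saline replicate 3, 1 fell without Ang II replicate 2, 1 of each without Ang II replicate 3 and 1 fell without NaBu replicate 6. Without saline replicate 2 the only call was Ppp1r3a, a glycogen-targeting subunit of a protein phosphatase, named after its value was seen, which fell by 1.99 on the log2 scale (SE 0.211, adjusted p = 0.0458).

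Camera with its preset correlation called several gene lists although no member was called. With fry and all 3 groups in the fit, no list was called in its direction in any comparison. The lowest fry adjusted p was 0.213 for Ang II against saline, 0.0755 for NaBu against Ang II and 0.11 for NaBu against saline. With only the 2 groups compared, fry called some lists for NaBu against Ang II. These were endoplasmic reticulum stress (median 0.23, fry adjusted p = 0.00908), hypertrophy (0.60, fry adjusted p = 0.0188) and lymphocyte markers (-0.32, fry adjusted p = 0.0442). Of 30 collagen matrix genes, 25 were lower with Ang II, with a median log2 difference of -0.54 (camera adjusted p = 4.68e-15, adjusted p = 0.339 with an estimated correlation). Over all genes edgeR called 0 of them, and 9 fell when adjusted over the list alone. The extremes were Thbs4 (-3.68, SE 1.01) and Ltbp2 (-2.59, SE 0.635) against Col6a3 (0.09) and Col4a1 (0.05). All 15 fibroblast markers were lower (median -0.29; camera adjusted p = 1.28e-10, adjusted p = 0.211 with an estimated correlation), among them Islr (-0.98, SE 0.173) and Mfap5 (-0.88, SE 0.314), and 7 fell adjusted over the list alone. Without saline replicate 2 the medians were -0.41 for collagen matrix and -0.19 for fibroblast markers. With saline replicates 2 and 3 both left out they were -0.03 and -0.09 and neither list was called (adjusted p = 0.547 and 0.089).

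The 10 erythroid transcripts, which come from red blood cell precursors and reticulocytes in blood, were all higher with Ang II (median 0.72; camera adjusted p = 3.15e-15, adjusted p = 0.211 with an estimated correlation). Of these, 7 rose adjusted over the list alone and 0 over all genes. Alas2, the first enzyme of red cell haem synthesis, was at 0.84 (SE 0.2) and Hbb at 0.50 (SE 0.222). All 14 antigen presentation genes (median 0.25; adjusted p = 1.4e-04, adjusted p = 0.211 with an estimated correlation) and 20 of 22 interferon response genes (median 0.19; 2.17e-05, adjusted p = 0.339 with an estimated correlation) were higher, led by RT1-Bb (0.51, SE 0.195) and Isg15 (0.58, SE 0.283), with 0 called over all genes or adjusted over the list alone. With saline replicates 2 and 3 both left out neither list was called (median 0.11 and adjusted p = 0.125 for antigen presentation, median 0.11 and adjusted p = 0.312 for interferon response). The 22 matrix crosslinking and turnover genes had a median of -0.17 (7.15e-04, adjusted p = 0.339 with an estimated correlation), from Timp4 (0.42, SE 0.09) to Timp1 (-0.92, SE 0.411); 2 rose and 3 fell adjusted over the list alone, and without saline replicate 3 the list was not called (median -0.12, adjusted p = 0.0601). Its median was -0.27 without saline replicate 2, and -0.07 and not called without saline replicates 2 and 3 (adjusted p = 0.744). The 19 TGF-beta signalling genes had a median of -0.19 (9.78e-05, adjusted p = 0.339 with an estimated correlation; 1 fell adjusted over the list alone), which was -0.03 and not called without saline replicate 2 (adjusted p = 0.0971) and -0.28 without saline replicate 1. All 9 atrial markers were lower (median -2.04, camera adjusted p = 5.01e-06, adjusted p = 0.339 with an estimated correlation), and 5 fell adjusted over the list alone. Without saline replicate 2 the atrial median was -0.53 and still called (camera adjusted p = 0.0105, adjusted p = 0.506 with an estimated correlation). With saline replicates 2 and 3 both left out it was 0.04.

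The direction or call of metabolic, contractile, hypertrophy and cell cycle lists depended on single libraries. Of 16 cell cycle genes 13 were lower with Ang II (median -0.15, camera adjusted p = 0.0493, adjusted p = 0.515 with an estimated correlation), with 0 called. Among other losses, the list was not called without saline replicate 3 (-0.13, camera adjusted p = 0.321) or Ang II replicate 2 (-0.10, camera adjusted p = 0.552). Its median was -0.36 without Ang II replicate 1. Of 26 fatty acid oxidation genes, 24 were higher with Ang II (median 0.14; camera adjusted p = 0.00125, adjusted p = 0.623 with an estimated correlation; 0 called over all genes or adjusted over the list alone). Without saline replicate 2 that median was -0.03 (adjusted p = 0.763). It was also not called without Ang II replicate 2 (0.07, adjusted p = 0.159) or Ang II replicate 3 (0.08, adjusted p = 0.114), and was 0.24, 0.25 and 0.26 without saline replicate 1, saline replicate 3 and Ang II replicate 1. Oxidative phosphorylation genes were not called (median 0.04, mean -0.01) and were lower without saline replicate 2 (-0.16, adjusted p = 4.6e-07, adjusted p = 0.506 with an estimated correlation). They were higher without saline replicate 1 (0.14, adjusted p = 0.0195), saline replicate 3 (0.19, adjusted p = 3.71e-05) or Ang II replicate 1 (0.15, adjusted p = 0.00909). These calls were lost as well, at adjusted p = 0.776, 0.647 and 0.827 with an estimated correlation. Glycolysis genes (median -0.01, adjusted p = 0.652) were lower without saline replicate 2, in 19 of 20 members (-0.14, adjusted p = 0.00132, adjusted p = 0.506 with an estimated correlation). Sarcomere genes (median -0.04, adjusted p = 0.704) were lower without saline replicate 2 (-0.20, adjusted p = 6.1e-04, adjusted p = 0.506 with an estimated correlation) and higher without saline replicate 3 (0.15, adjusted p = 0.00284, adjusted p = 0.647 with an estimated correlation). The 13 hypertrophy genes had a median of -0.21 (adjusted p = 0.022, adjusted p = 0.419 with an estimated correlation; 2 fell adjusted over the list alone). That median was 0.00 without saline replicate 3 (adjusted p = 0.444), -0.15 without Ang II replicate 1 (adjusted p = 0.0889), -0.11 without Ang II replicate 2 (adjusted p = 0.0591), -0.36 without saline replicate 2, where 7 fell adjusted over the list alone, and -0.08 without saline replicate 1.

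The comparison of NaBu with Ang II alone asks what the butyrate salt adds to the hormone. Mapkapk2, a kinase downstream of p38, rose from 183 ± 15.1 to 440 ± 22.4 CPM (n = 3; log2 1.27, SE 0.19, adjusted p = 0.0372). Myh7b, a slow-type myosin heavy chain, fell from 332 ± 43.2 to 142 ± 21.6 CPM (log2 -1.23, SE 0.16, adjusted p = 0.0269), and Flrt1, a transmembrane protein with leucine-rich repeats, fell from 91.5 ± 11 to 27.8 ± 5.17 CPM (log2 -1.72, SE 0.18, adjusted p = 0.0158). Nppb, the natriuretic peptide released by stretched ventricle, rose from 120.7 ± 19 to 196.2 ± 23.4 CPM (log2 0.70, SE 0.145, adjusted p = 0.0469). Crkl, an adaptor protein of tyrosine kinase signalling, was listed at 0 in all 6 saline and Ang II libraries and at 653 to 883 estimated counts in the NaBu libraries, at least 38.6-fold higher against a floor of 3 fragments, or 12 estimated counts, per library.

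With NaBu 100 genes rose and 148 fell against Ang II, with median changes of 1.5-fold and 1.61-fold, and 3458 genes had an unadjusted p under 0.05. The groups did not overlap in 35.6% of genes where chance gives 10%. Apart from Crkl and Mapkapk2 the largest rises were of Pnpla3 (1.27 on the log2 scale), a lipase related to adipose triglyceride lipase, Tceal8 (0.89), Tmem126a (0.88), Cks1b (0.78), Scrn3 (0.75), Acsf2 (0.74), Tank (0.73) and Prkar2a (0.73), a regulatory subunit of protein kinase A. Apart from Flrt1 and Myh7b the largest falls were of Itga2b (-1.99), the platelet integrin alpha chain, Col11a2 (-1.90), Odf2l (-1.38), Pdzd9 (-1.29), Exnef (-1.28), Lcat (-1.25), which esterifies cholesterol in plasma, Adam33 (-1.24) and Jmjd7 (-1.12). The adjusted p-values of the genes in these last lists of rises and falls lay between 0.0248 (Jmjd7) and 0.0447 (Acsf2). Upper-quartile scaling gave 87 rises and 209 falls (29.4% rises against 40.3%), and scaling by total count gave 2 and 2, where the median of all genes was -0.133 against -0.025 with TMM.

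These calls depended on each Ang II and NaBu library and on saline replicate 1. Rises and falls numbered 10 and 34 without saline replicate 1, 968 and 514 without saline replicate 2, 270 and 290 without saline replicate 3, 1 and 0 without Ang II replicate 1, 2 and 2 without Ang II replicate 2, 1 and 1 without Ang II replicate 3, 3 and 2 without NaBu replicate 2, 1 and 2 without NaBu replicate 4, and 2 and 2 without NaBu replicate 6. Saline libraries enter through the shared estimate of the spread. Of the 20 genes in this ranking, Crkl included, 20 kept their call without saline replicate 2 or 3, 8 without saline replicate 1 and between 1 and 3 without any single Ang II or NaBu library, and none changed sign. All 248 called genes were also called without saline replicate 2 and without saline replicate 3. The highest transcript per gene gave 1 rise and 2 falls, and only the 2 groups compared gave 1082 and 720.

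**Figure D2:**
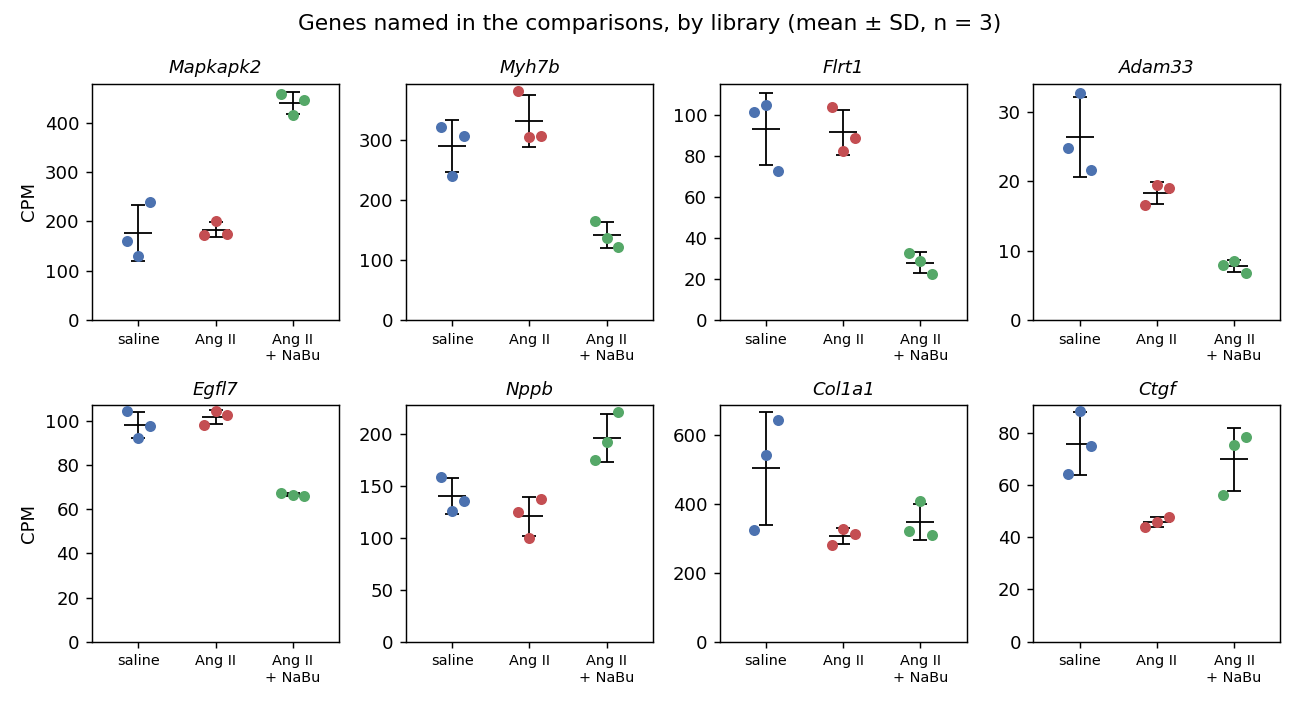
CPM of 8 genes in each library, with 1 point per library and the group mean ± SD (n = 3) as lines; each vertical axis starts at 0. Mapkapk2 averages 440 CPM with NaBu against 183 CPM with Ang II, while the saline and NaBu libraries overlap for Col1a1 and Ctgf.

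Most listed genes of energy metabolism were higher with NaBu than with Ang II. Of 40 oxidative phosphorylation genes, 39 were higher (median 0.35; camera adjusted p = 7.33e-07, adjusted p = 0.61 with an estimated correlation), but 0 were called by edgeR over all genes and 0 adjusted over the list alone. Uqcrfs1, the iron-sulphur subunit of complex III, was at 0.60 (SE 0.194). Without saline replicate 2, 14 members rose. Of 26 fatty acid oxidation genes, 25 were higher (median 0.36; 2.13e-06, adjusted p = 0.61 with an estimated correlation), with Etfdh at 0.74 (SE 0.201) and Acsl1 at 0.72 (SE 0.313); 0 rose over all genes, 3 adjusted over the list alone and 9 over all genes without saline replicate 2. This median was 0.24 without Ang II replicate 1. All 20 glycolysis genes were higher (median 0.29; 3.86e-04, adjusted p = 0.61 with an estimated correlation), led by the glucose transporter Slc2a1 (0.45, SE 0.18), with 0 called over all genes or adjusted over the list alone and 6 that rose without saline replicate 2. All 10 ketone and butyrate metabolism genes were higher (median 0.31; 0.0283, adjusted p = 0.61 with an estimated correlation; 0 called over all genes or adjusted over the list alone), led by Oxct1, the enzyme that activates ketone bodies (0.56, SE 0.231). That list was not called without saline replicate 3 (adjusted p = 0.0649), Ang II replicate 1 (median 0.16, adjusted p = 0.177), NaBu replicate 4 (adjusted p = 0.0513) or NaBu replicate 6 (adjusted p = 0.108). It was also not called with ribosomal RNA genes left out, and 4 members rose without saline replicate 2. Outside energy metabolism, 17 of 21 antioxidant genes were higher (median 0.19, camera adjusted p = 0.0171, adjusted p = 0.61 with an estimated correlation). Of these 0 were called over all genes or adjusted over the list alone, and 4 rose over all genes without saline replicate 2. The antioxidant median was 0.35 without Ang II replicate 3.

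Some hypertrophy and contractile genes were also higher with NaBu. Of 13 hypertrophy genes 10 were higher. Nppb and Fhl1 (0.57, SE 0.117, adjusted p = 0.0456) rose over all genes and 4 rose adjusted over the list alone, and Acta1 was at 0.81 (SE 0.526) and Nppa at 0.86 (SE 1.09). The list had a median of 0.60 (camera adjusted p = 0.00361, adjusted p = 0.61 with an estimated correlation), and 6 members rose without saline replicate 2. Of 15 sarcomere genes, 13 were higher (median 0.34; 0.0198, adjusted p = 0.816 with an estimated correlation; 0 called over all genes or adjusted over the list alone), with Myl3 at 0.63 (SE 0.3) and Actc1 at 0.60 (SE 0.243). The sarcomere list was not called without NaBu replicate 2 (median 0.27, adjusted p = 0.0634), and without saline replicate 2 6 members rose and 1 fell. The 16 adult excitation and contraction genes were not called (median 0.22, adjusted p = 0.257), with 0 called over all genes and 2 rises and 3 falls adjusted over the list alone; without saline replicate 2 4 rose and 3 fell over all genes. Herpud1, a membrane protein of the endoplasmic reticulum stress response, rose (0.49, SE 0.103, adjusted p = 0.0476), 1 of 14 members of its list, where 3 rose adjusted over the list alone. That list had a median of 0.23 (0.0198, adjusted p = 0.61 with an estimated correlation), was not called without NaBu replicate 4 (0.21, adjusted p = 0.0649) and had 6 rises without saline replicate 2.

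Listed endothelial and erythroid transcripts were lower with NaBu than with Ang II, and few of them were called. Of 17 smooth muscle genes 15 were lower, but that list was not called (median -0.23, camera adjusted p = 0.266). Adjusted over the list alone, 2 smooth muscle genes rose and 1 fell. All 15 endothelial markers were lower (median -0.25; camera adjusted p = 1.73e-04, adjusted p = 0.61 with an estimated correlation), and Egfl7, a protein secreted by endothelial cells, fell from 101.7 ± 3.3 to 66.5 ± 0.728 CPM (log2 -0.61, SE 0.084, adjusted p = 0.0296). It was the 1 member called over all genes, 3 fell adjusted over the list alone and 4 fell over all genes without saline replicate 2; the median was -0.15 without Ang II replicate 1. All 10 erythroid transcripts were lower (median -0.50; 0.00304, adjusted p = 0.61 with an estimated correlation), with Hbb at -0.69 (SE 0.222); 0 fell over all genes, 1 adjusted over the list alone and 1 over all genes without saline replicate 2. This list was not called without Ang II replicate 3 (-0.31, adjusted p = 0.0742). Of 22 interferon response genes 20 were lower (median -0.27; 0.00304, adjusted p = 0.61 with an estimated correlation), with Oas1a at -0.86 (SE 0.282), 0 called over all genes and 1 that fell adjusted over the list alone; 1 fell over all genes without saline replicate 2.

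Collagen matrix genes were not called between NaBu and Ang II, and some lay far apart. The 30 members had a median log2 difference of 0.12 and a mean of 0.40, with 20 higher (camera adjusted p = 0.163). They ran from Thbs4 (3.08, SE 0.986) and Comp (1.77, SE 1.17) to Col5a3 (-0.13, SE 0.1). In edgeR 0 were called over all genes or adjusted over the list alone. The 15 fibroblast markers had a median of -0.03 (adjusted p = 0.843). The collagen list was called, as higher, without saline replicate 1 (0.12, adjusted p = 0.033), without NaBu replicate 6 (0.19, adjusted p = 0.021) and without saline replicates 2 and 3 (0.10, adjusted p = 0.0294). None of these calls held, at adjusted p = 0.625, 0.82 and 0.637 with an estimated correlation. With only the 2 groups compared the collagen matrix list was also called (0.11, adjusted p = 0.0259, adjusted p = 0.64 with an estimated correlation). Col1a1 (0.18, SE 0.217), Col3a1 (0.14, SE 0.194), Postn (1.38, SE 0.697, adjusted p = 0.272) and Ctgf (0.61, SE 0.148, adjusted p = 0.0667) were not called, although Postn and Ctgf were higher in each NaBu library than in each Ang II library (2.61-fold and 1.52-fold). Both passed with only the 2 groups compared and without saline replicates 2 and 3. The adjusted p of Postn ranged from 0.042 to 0.577 over the alternatives. Ctgf also passed without saline replicate 2 (0.63, adjusted p = 0.0219) and with DESeq2 (adjusted p = 0.00327; 0.00327 to 0.244 over the alternatives). Timp4, an inhibitor of matrix metalloproteinases expressed in heart, fell from 81 ± 1.79 to 55.9 ± 1.78 CPM (log2 -0.54, SE 0.09, adjusted p = 0.0415), 1 of 22 crosslinking and turnover genes. Of the clock genes Per3 fell (-0.73, SE 0.151, adjusted p = 0.046). Tgfb1 (-0.07), Hdac5 (-0.08), Myh6 (0.10), Myh7 (0.01), Acta2 (-0.34) and Ptgs2 (1.10, SE 0.597) were not called. The 6 called list members, Nppb, Fhl1, Herpud1, Egfl7, Per3 and Timp4, all kept their call without saline replicate 2 or 3, 2 kept it without saline replicate 1 and 0 kept it without any single Ang II or NaBu library.

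**Figure D3:**
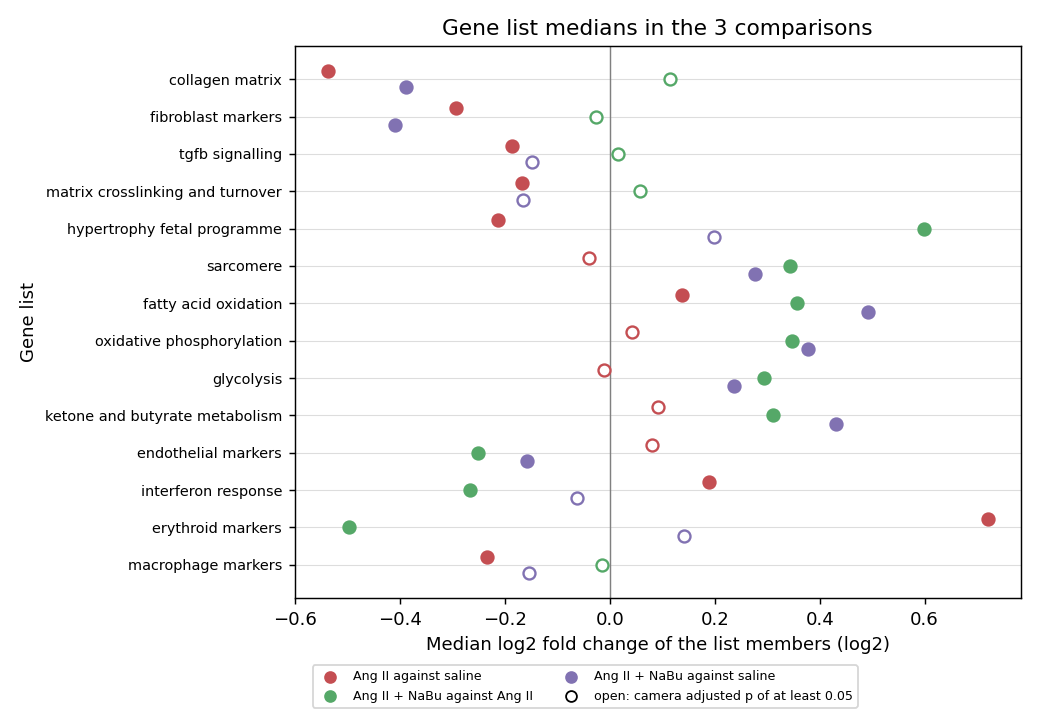
Median log2 fold change of the members of 14 gene lists in the 3 comparisons; filled points have a camera adjusted p under 0.05 with the preset correlation and open points do not. Collagen matrix genes lie at -0.54 for Ang II against saline and at 0.12 for NaBu against Ang II, and oxidative phosphorylation genes at 0.04 and 0.35; no filled point stays called with an estimated correlation.

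The comparison of NaBu with saline gives the distance of the combined treatment from the control. Macrod2, an ADP-ribose hydrolase, rose from 62.5 ± 6.85 to 140 ± 9.25 CPM (n = 3; log2 1.16, SE 0.11, adjusted p = 0.00504), and Mapkapk2 rose from 177 ± 55.9 to 440 ± 22.4 CPM (log2 1.32, SE 0.19, adjusted p = 0.0139). Adam33, a metalloproteinase of mesenchymal cells, fell from 26.4 ± 5.78 to 7.77 ± 0.906 CPM (log2 -1.77, SE 0.17, adjusted p = 0.00504), and Plekha6 fell from 102 ± 3.65 to 35.3 ± 4.06 CPM (log2 -1.53, SE 0.19, adjusted p = 0.0123). Crkl was again listed at 0 in saline. Other large rises were of Hmga1 (1.10), Tmem69 (1.07), Bdnf (1.07), a neurotrophin, Scrn3 (1.02), Apool (1.02), a protein of mitochondrial cristae, and Frat1 (1.01). Other large falls were of Flrt1 (-1.74), Col11a2 (-1.72), Adamtsl2 (-1.48), Setd4 (-1.33), Lcat (-1.32), Sec16b (-1.20; -0.76 without saline replicate 2) and Klhl17 (-1.19). Bmp10 averaged 0.216 ± 0.21 CPM against 223 ± 367 CPM in saline (adjusted p = 0.0376), with 646 CPM in saline replicate 2, 22.2 in saline replicate 3 and 0.42 in saline replicate 1. Its log2 difference was -9.97 (SE 2.27), and without saline replicate 2 it was -5.65 (SE 1.34) and not called (adjusted p = 0.0537).

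In all 465 genes rose and 317 fell against saline, with median changes of 1.49-fold and 1.56-fold. There were 3807 genes with an unadjusted p under 0.05, and the groups did not overlap in 28.6% of genes where chance gives 10%. Upper-quartile scaling gave 383 rises and 396 falls (49.2% rises against 59.5%), and total count scaling gave 287 and 124 (69.8%) with an all-gene median of -0.109 against -0.051. Only 5 rose and 4 fell with only the 2 groups compared, and 24 and 9 with the highest transcript per gene. Ang II libraries, which are outside this comparison, enter through the shared estimate of the spread. The saline libraries were less alike than the others, so that estimate may be too small for saline. The number of calls against saline therefore rests on the shared estimate. Rises and falls were 233 and 179 without saline replicate 1, 293 and 141 without saline replicate 2, 769 and 534 without saline replicate 3, 440 and 198 without Ang II replicate 1, 138 and 65 without Ang II replicate 2, 143 and 77 without Ang II replicate 3, 5 and 4 without NaBu replicate 2, 68 and 43 without NaBu replicate 4, and 3 and 3 without NaBu replicate 6. Of the 20 genes in this ranking, 17, 18 and 20 kept their call without saline replicates 1, 2 and 3, 19, 14 and 15 without Ang II replicates 1, 2 and 3, and 4, 12 and 5 without NaBu replicates 2, 4 and 6, and none changed sign.

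All 26 fatty acid oxidation genes were higher with NaBu than with saline (median 0.49; camera adjusted p = 4.27e-11, adjusted p = 0.636 with an estimated correlation). Of these, 4 rose over all genes and 17 adjusted over the list alone: Acot2 (0.91, SE 0.163), a mitochondrial acyl-CoA thioesterase, Etfdh (0.88, SE 0.202), Ucp3 (0.82, SE 0.14) and Acadvl (0.59, SE 0.138) were the 4. Adjusted over the list alone, 7 rose without saline replicate 2. Oxidative phosphorylation genes had a median of 0.38 (7.41e-08, adjusted p = 0.636 with an estimated correlation) and 35 of 40 were higher, with 2 called, Uqcrfs1 (0.80, SE 0.194) and Cox6c (0.75, SE 0.161), and 3 adjusted over the list alone; without saline replicate 2 the median was 0.19 and 1 was called. Ketone and butyrate metabolism genes (median 0.43; 0.00404, adjusted p = 0.636 with an estimated correlation) had 0 called and 3 that rose adjusted over the list alone, and a median of 0.26 without saline replicate 2. Of 21 antioxidant genes (median 0.26; 0.00404, adjusted p = 0.636 with an estimated correlation), Gpx1 (0.78, SE 0.166), Prdx1 (0.52, SE 0.124) and Txnrd1 (0.38, SE 0.094) rose, and 6 rose adjusted over the list alone. None of the 3 was called without saline replicate 2. Of the 9 fits without 1 library, Gpx1 and Prdx1 were called in 2 each and Txnrd1 in 0. Glycolysis (median 0.24; 0.00404, adjusted p = 0.636 with an estimated correlation; 0 members called over all genes or adjusted over the list alone) was not called without saline replicate 2 (0.12, adjusted p = 0.0691) and was at 0.40 without saline replicate 3. Sarcomere genes (0.28; 0.0132, adjusted p = 0.683 with an estimated correlation; 0 called over all genes, 1 up and 1 down adjusted over the list alone) were not called without saline replicate 2 (0.15, adjusted p = 0.464) and were at 0.49 without saline replicate 3.

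Most listed fibroblast, collagen matrix and smooth muscle genes were lower with NaBu than with saline, and few were called. Of 22 matrix crosslinking and turnover genes 18 were lower, but that list was not called (median -0.17, camera adjusted p = 0.0758). It was called without saline replicate 1 (camera adjusted p = 0.00413) or NaBu replicate 4 (0.0367), and neither call held with an estimated correlation (adjusted p = 0.392 and 0.621). All 15 fibroblast markers were lower (median -0.41; camera adjusted p = 0.00197, adjusted p = 0.636 with an estimated correlation), of which Fbln2 fell over all genes (-0.57, SE 0.137) and 2 fell adjusted over the list alone. Of 30 collagen matrix genes, Col14a1 (-0.62, SE 0.116) and Fbn1 (fibrillin-1; -0.56, SE 0.131) fell, 2 fell adjusted over the list alone, and the median was -0.39 (0.00526, adjusted p = 0.636 with an estimated correlation). Without saline replicate 2 the medians were -0.20 for fibroblast markers, with 0 called, and -0.25 for collagen matrix, with 1 called, and without saline replicate 3 the collagen list was not called (-0.16, adjusted p = 0.317). With both of these libraries left out they were -0.05 and 0.14, neither called. Smooth muscle genes (-0.49; 0.0175, adjusted p = 0.636 with an estimated correlation) were not called without saline replicate 2 (-0.20, adjusted p = 0.141), saline replicate 3 (-0.56, adjusted p = 0.0771) or NaBu replicate 4 (-0.45, adjusted p = 0.0968), and Des (desmin) rose within the list (0.65, SE 0.156), where 1 rose and 3 fell adjusted over the list alone. Complement and coagulation genes (-0.48; 0.00983, adjusted p = 0.636 with an estimated correlation; 0 called over all genes or adjusted over the list alone) were not called without saline replicate 2 (-0.16, adjusted p = 0.141) or saline replicate 3 (-0.45, adjusted p = 0.0533). Endothelial markers (-0.16; 0.0111, adjusted p = 0.636 with an estimated correlation) were all lower and Egfl7 fell (-0.56, SE 0.084), with 2 that fell adjusted over the list alone. They were not called without saline replicate 1 (-0.12, adjusted p = 0.0586) or NaBu replicate 4 (-0.15, adjusted p = 0.0618) and were at -0.24 without NaBu replicate 2. All 9 atrial markers were lower (-1.64; 0.0194, adjusted p = 0.636 with an estimated correlation; Bmp10 called and 5 that fell adjusted over the list alone), but at -0.14 and not called without saline replicate 2 (adjusted p = 0.379).

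The calcium pump regulator Pln (phospholamban) rose from 2614 ± 642 CPM in saline to 4655 ± 261 CPM (log2 0.83, SE 0.171, adjusted p = 0.0305), as did the gap junction gene Gja1 (0.51, SE 0.111). Among 18 circadian clock genes Per3 (-0.77, SE 0.151), Per2 (-0.60, SE 0.133) and Npas2 (-0.59, SE 0.127) fell, the list itself was not called (median 0.02, mean -0.05, camera adjusted p = 0.826), and 1 rose and 3 fell adjusted over the list alone. Over all genes edgeR called 0 clock genes without saline replicate 2. Col1a1 (-0.54, SE 0.218, adjusted p = 0.164), Acta2 (-0.87, SE 0.355, adjusted p = 0.167) and Nppa (-4.23, SE 1.23, adjusted p = 0.071) were not called, but each passed without saline replicate 1 (adjusted p = 0.0406, 0.04 and 0.04). Nppa also passed without saline replicate 3 (adjusted p = 0.0429) and with DESeq2 (adjusted p = 0.00956; 0.00956 to 0.792 over the alternatives). Nppb (0.49, SE 0.145, adjusted p = 0.0755) was not called with edgeR and was called with DESeq2 (adjusted p = 0.0113; 0.0113 to 0.431 over the alternatives). Col3a1 (-0.31, SE 0.194), Postn (-0.70, SE 0.677), Ptgs2 (-1.08, SE 0.578), Ctgf (-0.12, SE 0.147), Tgfb1 (-0.02), Hdac5 (-0.04), Myh6 (-0.04) and Myh7 (0.33) were not called with edgeR either. Over the lists, 29 members were called. Of these 9, 11 and 24 kept their call without saline replicates 1, 2 and 3, 18, 4 and 5 without Ang II replicates 1, 2 and 3, and 0, 1 and 0 without NaBu replicates 2, 4 and 6.

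The design also asks how far NaBu moved genes back toward their saline level. Of 65 genes at least 2-fold higher with Ang II than with saline, 34 (52.3%) were at least 0.5 of the way back with NaBu and 3 were at least 1.5-fold further away. Of 179 genes at least 2-fold lower, 67 (37.4%) were that far back and 16 further away. Ang II stands in both differences, so return arises by chance: simulated groups without any change gave 39.9% and 57.3%. The simulation gave each gene the same spread in all groups, while the real saline libraries were less alike than the others. Its shares are therefore only a rough guide to the return expected by chance here. Without saline replicate 2 there were 160 higher genes with 62 back (38.8%) and 135 lower genes with 75 back (55.6%). Without Ang II replicate 2 the genes back numbered 57 and 108, and without Ang II replicate 3 the lower ones back numbered 108. These are counts and not shares, and leaving out a library can also change how many genes pass 2-fold. They therefore do not show more or less return. Pnpla3 went from 7.01 ± 1.78 CPM in saline to 3.1 ± 0.0789 with Ang II and 7.49 ± 1.06 with NaBu. Other genes moved onward: Macrod2 was at 62.5, 94.5 and 140 CPM and Adam33 at 26.4, 18.4 and 7.77 CPM in the same order. These 3 examples were chosen after their values were seen.

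The 2 NaBu comparisons shared 84 genes that rose and 119 that fell, where independent lists would share 3 and 3 and simulated unchanged groups 0. Across 13681 genes their log2 changes correlated at r = 0.638 (0.512 simulated) with a covariance of 0.179 (0.064 simulated). For Ang II against saline beside NaBu against Ang II r was -0.35 (-0.488 simulated) and the covariance -0.081 (-0.06 simulated), and beside NaBu against saline r was 0.498 (0.499 simulated) and the covariance 0.124 (0.062 simulated). Genes are not independent replicates, and 3 shared libraries leave no split with 2 on each side, so part of each excess may come from them. The shared group was also split unevenly, 1 library to one comparison and the other two to the other, a test chosen after the data were seen. Over the 6 such splits of NaBu the covariance of the 2 NaBu comparisons averaged 0.099 (0.083 to 0.112; 0.001 simulated). For Ang II against saline it averaged -0.012 (-0.031 to 0.006) beside NaBu against Ang II and -0.002 (-0.021 to 0.032) beside NaBu against saline, with 0 simulated for both. A difference in processing of the NaBu table would enter both NaBu comparisons in these splits too.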

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

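The tests with rRNA genes left out, counts divided by 4, genes at 0 left out, thinned libraries, a span offset, or saline replicates 2 and 3 left out were chosen after the data were seen; the others were fixed before. Prior counts of 0.1 and 5 changed no count of calls, which was fixed in advance, since the prior enters the fold changes and not the p-values. Counts within 1.5 times are not listed. Where a count or direction changed, the cause was not tested. DESeq2 size factors and median-of-ratios factors are a single setting, and fold thresholds without a test were run only for reversal, since the 3 comparisons have a test. Depth limits the low genes, where 1 fragment was worth about 4 counts.

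For NaBu against Ang II, genes that rose and fell numbered 205 and 354 at a mean of at least 5 CPM, 2 and 2 with total count scaling, 1 and 2 with the highest transcript per gene, 872 and 649 with DESeq2, 1082 and 720 with only the 2 groups compared, 54 and 75 with the span offset, and 1020 and 675 without saline replicates 2 and 3. The rises numbered 159 with counts divided by 4 and 167 without genes listed at 0. For NaBu against saline they numbered 287 and 124 with total count scaling, 24 and 9 with the highest transcript, 1240 and 767 with DESeq2, 5 and 4 with only the 2 groups, and 55 and 54 without saline replicates 2 and 3, and 577 fell at a mean of at least 5 CPM. For Ang II against saline, DESeq2 gave 23 and 34, only the 2 groups 1 that fell, and the fit without saline replicates 2 and 3 gave 10 and 1. For reversal, genes higher and lower that came back numbered 7 and 16 at a mean of at least 5 CPM, 157 and 191 at a 1.5-fold change and 4 and 32 at a 3-fold change, with 42 lower ones without genes listed at 0 and 73 higher ones without saline replicates 2 and 3.

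Leaving out 1 library gave 0 to 4 rises and 0 to 3 falls for Ang II against saline, 1 to 968 and 0 to 514 for NaBu against Ang II, and 3 to 769 and 3 to 534 for NaBu against saline. For reversal, the genes back ranged from 30 to 62 higher and 49 to 108 lower ones, as counts and not as shares of the genes past 2-fold. For Ang II against saline the list medians ranged from -0.031 to 0.164 (cytokines and adhesion), -0.029 to 0.262 (fatty acid oxidation), -0.161 to 0.188 (oxidative phosphorylation), -0.36 to 0.004 (hypertrophy) and -0.204 to 0.149 (sarcomere). Without saline replicates 2 and 3 the lone saline library is assumed to vary like the other groups. Ang II against saline then turned to 0.04 for atrial markers, 0.068 for complement, -0.03 for fatty acid oxidation, -0.11 for oxidative phosphorylation, 0.082 for smooth muscle and 0.039 for TGF-beta signalling. NaBu against saline turned to 0.149 for atrial markers, 0.142 for collagen matrix, 0.026 for complement and 0.055 for smooth muscle.

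Same-numbered saline and Ang II libraries did not deviate together (correlations of -0.02, -0.06 and -0.03), so the numbers do not pair them, and no library correlated best with its own number. With the replicate number as a block, Ang II against saline had 0 rises and 0 falls in edgeR (488 genes at an unadjusted p under 0.05), where the same 2 groups without the block had 1 fall (673 genes). No paired analysis was possible because the NaBu columns carry other numbers, for the NaBu comparisons and for reversal.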

Other observations

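The tests of atrial tissue, of a ventricular stress programme, of reads assigned to other names, of ways to part the libraries into sets, of depth and of gene span were chosen after the result was seen.

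Several inflammatory cell and signalling lists were called in at least 1 comparison. With Ang II against saline, 17 of 23 macrophage markers were lower (median -0.23, camera adjusted p = 0.00481, adjusted p = 0.433 with an estimated correlation), with C1qa at -0.47 (SE 0.142). That list was not called without saline replicate 2 (-0.09, adjusted p = 0.261) or Ang II replicate 3 (-0.15, adjusted p = 0.0949), and was at -0.14 without Ang II replicate 2. Of 18 complement and coagulation genes 15 were lower (-0.24, adjusted p = 0.00125, adjusted p = 0.446 with an estimated correlation), with C6 at -1.35 (SE 0.481); the median was -0.41 without saline replicate 1 and -0.11, not called, without saline replicate 2 (adjusted p = 0.349). The 6 neutrophil and mast cell markers had a median of 0.40 (adjusted p = 0.0118, adjusted p = 0.339 with an estimated correlation), with Cpa3 at 1.44 (SE 0.477). This was not called without saline replicate 1 (0.38, adjusted p = 0.131), saline replicate 3 (0.30, adjusted p = 0.0728), Ang II replicate 1 (0.38, adjusted p = 0.0889) or Ang II replicate 3 (0.14, adjusted p = 0.304). Each of these 3 lists had 0 members called by edgeR in this comparison, over all genes or adjusted over the list alone; without saline replicate 2, 2 neutrophil and mast cell markers rose adjusted over the list alone.

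With NaBu against Ang II the same 6 neutrophil and mast cell markers were all lower (median -0.53, camera adjusted p = 0.0234, adjusted p = 0.61 with an estimated correlation), with S100a8 at -0.75 (SE 0.238). They were not called without Ang II replicate 1 (-0.48, adjusted p = 0.0601), Ang II replicate 3 (-0.34, adjusted p = 0.244) or NaBu replicate 4 (-0.46, adjusted p = 0.0964). Of 24 immediate early genes 20 were lower (-0.30, adjusted p = 0.038, adjusted p = 0.61 with an estimated correlation), with Fos at 7.4 ± 1.82 against 16.5 ± 2.25 CPM (log2 -1.16, SE 0.45). That list was not called without Ang II replicate 1 (-0.14, adjusted p = 0.315), NaBu replicate 2 (-0.33, adjusted p = 0.0666) or NaBu replicate 4 (-0.30, adjusted p = 0.0545). Both lists had 0 members called here over all genes or adjusted over the list alone; without saline replicate 2, 1 immediate early gene rose and 3 fell over all genes. The 15 histone deacetylases, among them the enzymes butyrate inhibits, went both ways, with 7 higher and 8 lower (median -0.08, mean 0.01, camera adjusted p = 0.438). Hdac10 (-0.53, SE 0.176) and Hdac7 (-0.48, SE 0.12) were lowest, and 1 fell adjusted over the list alone while edgeR called 0 over all genes.

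Atrial transcripts were high in saline replicate 2. For a raised ventricular stress programme, 0 of Nppb, Myh7 and Acta1 were above the highest other library there. They were at 0.847, 0.361 and 0.159 of the median of the other libraries. The ventricular transcripts Myl2 and Myl3 were also low there, at 0.421 and 0.373 of that median. A lower amount of ventricular RNA could therefore hide a rise, and this test cannot decide. A candidate explanation is atrial tissue in the library: the median log2 ratio of the atrial list was 2.94, with Nppa at 3460 CPM and Myl7 at 789 CPM. Ventricle also expresses some members of that list, such as Nppa.

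A few genes were at 0 throughout a group and at 10 or more estimated counts in each library elsewhere. LOC100910581 and Ppp1r35 were at 0 in saline, LOC100911537 in Ang II and Crkl in all but NaBu. Of the 4 genes, 3 set saline or Ang II apart. NaBu activity does not account for LOC100910581 and Ppp1r35, which were counted with Ang II alone too. It is not decided for LOC100911537, which was at 17 to 339 estimated counts with NaBu and could have been restored by it. Reads assigned to other names in some libraries may account for them: 149 genes were at 0 in 1 library and at 100 or more estimated counts in another of the same group. Tables processed separately cannot be told apart from other causes: the 3 real groups held 4 such genes in sum, and of the 280 ways to part the 9 libraries into sets of 3, 82 held as many (highest other 7, mean of the others 2.71). The bound written beforehand was wrong, since it set a sum over 3 sets against single sets. For Crkl and LOC100911537 a NaBu effect stays open.

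NaBu differed broadly from Ang II. For depth, 244 genes were called with every library thinned to the smallest. The thinning drew single estimated counts, while 1 fragment was worth about 4 of them. It therefore did not bring the libraries to an equal depth in fragments, and this test cannot decide. A trend with gene span is argued against as the whole cause: in the 230 of 248 called genes with a span the median change was 0.632 before and 0.631 after its removal, while the median SE went from 0.117 to 0.124 and 127 stayed called; why the other calls ended was not tested. Separate processing of the tables cannot be told apart from the treatment: 21.8% of genes with 1 transcript and 20.6% of matched genes with several had an unadjusted p under 0.05, but a separate run could also move genes with 1 transcript, so the bound written beforehand was wrong. A NaBu effect also stays open.

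Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. Ang II against saline called 0 genes and the highest other split 7, so all 10 splits called as many. NaBu against Ang II called 248 (highest other 2) and NaBu against saline 782 (highest other 1), each the 1 split of 10 with as many.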
